A study of Drosophila melanogaster with 12 samples.

How the data were processed

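The samples were 12 spotted cDNA arrays of 2 colours, 4 each for day 8, day 10 and day 14, of male heads after 7 days on PTZ and 1, 3 or 7 days on normal food, each against untreated heads. Per the labels' protocols, total RNA came from pools of sieved frozen heads, was copied to cDNA and was transcribed into Cy3- or Cy5-labelled RNA. The slides came from a spotted Drosophila cDNA collection, and spot numbers run in pairs of the same clone.

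The values are deposited log2 ratios, 1 per spot and array. Per the labels, the authors normalized the data by ratio. Per the series text, images were quantified with GenePix Pro 6.0 and normalized by ratio in Acuity 4.0, spots were kept with under 3% saturated pixels, a regression R2 of at least 0.6 between the channels and a signal to noise of at least 3, and spots measured in at least 3 of 4 replicates went to SAM 2.21. The base of the logarithm is not given in the sources used here, and 2 was assumed. Intensities and backgrounds of the spots were not analysed here, so dim spots could not be weighed apart from the filters above.

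Of 27648 spots, 15116 carry 1 gene name in the platform table, 102 carry several and were left out, and 12430 are unnamed here. Symbols of 14894 spots were brought up to date through gene numbers in a RefSeq table. The spots of a gene were averaged on each array, which gave 6793 genes, of which 5291 entered the fit. The column medians were examined before any test was run. Those of day 14, up to 1.588, were far from 0, so the median of each array was set to 0 in all results, and the values as deposited, which had been planned as the starting point, became the alternative. The form of the day 8 tests was also set after its columns were seen. Tests, gene lists, alternatives and the rule for naming genes were otherwise fixed before the data were examined, except those said to be chosen afterwards.

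The 4 day 8 columns were identical wherever 2 of them held a value, at a tolerance of 0, and entered as 1 sample, their mean. They had been planned as 4 arrays, so the tests of that day took their form after the columns were seen. A fit of a mean per day to the 9 samples was made with limma 3.58.1 (lmFit and eBayes, R 4.3.3, prior degrees of freedom 5.10). All days shared 1 estimate of the spread, and the lone day 8 sample is assumed to vary like the arrays of the other days, although its twin spots differed more. A gene was tested at a day with a value in at least 3 of its 4 columns, as the series text has it. The mean of each day and of the 3 days was tested against 0, and the 3 differences between days were tested in the same fit. A call is an adjusted p under 0.05 after Benjamini-Hochberg adjustment over the genes tested in that comparison. The replicates of days 10 and 14 are biological per the labels. The untreated heads are the other channel of each array, so their own spread is part of each ratio. The replicate numbers were checked for pairing between days 10 and 14 and do not pair the arrays.

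There were 32 gene lists, fixed beforehand, of neuronal signalling, energy and stress metabolism, defence, clock, sense organs and of markers of tissues that sieved male heads could hold. Lists with at least 5 tested genes were tested per day with cameraPR on the moderated statistics, with an inter-gene correlation of 0.01, and adjusted over the lists of that day. An estimated correlation could be had for 20 lists at days 10 and 14. At day 8 the list median was set against 10000 random lists of the same size. Dye terms were not in the fit, because which 2 of 4 arrays were swapped is not given in the sources used here.

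Genes were named by a rule. For each day it takes the 10 highest and 10 lowest called genes with 1 sign on every array, or the 5 smallest p of a direction with fewer than 3 calls. For the mean of the 3 days and the differences it takes the 5 highest and 5 lowest called, or the 3 smallest p. It adds 2 members of each list that passed and the GABA genes Gad1, Gabat and Lcch3, while Rdl, VGAT and Grd had no tested value. Genes named outside this rule are said to have been named after their values were seen.

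The test was checked on simulated data made from the spread of the real samples. At a log2 change of 1 it found 77.0% of changed genes at day 8, 99.7% at day 10 and 99.7% at day 14. At a change of 0.5 it found 7% at day 8, 51.9% at day 10 and 54.0% at day 14. Wrong calls made up 5.20% of calls at day 10 and 4.52% at day 14. The simulated day 8 has the spread of the other days, so the shares found there hold only under that assumption, and its wrong calls say nothing about the real day 8. A shift of 0.15 of the oxidative phosphorylation genes at day 14 was found in 20 of 20 simulations. The simulated noise was independent between genes and, at days 10 and 14, between arrays. The real list had an estimated correlation of 0.14, and day 10 arrays correlated in pairs at an r of 0.51 and 0.56. The shares found and the wrong calls therefore need not hold for the real days 10 and 14.

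Alternatives were the values as deposited, equal spread of the arrays, filters of 2 and of 4 columns, 1 probe per gene or each probe alone, only the days compared, SAM with 16 sign flips, robust spread, array weights, a replicate block, the slide series as a random block, dye terms and turned signs in 3 pairings, other correlations in the list test, an adjusted p of 0.1, and each replicate left out. After seeing the data, spots whose twin differed by more than 1, medians of print blocks of 576 spots and of places within them, the mean of days 10 and 14 alone, a day 8 spread raised by the ratio of the SDs of twin spots, and dye terms in the difference and dye terms and turned signs in the lists were added. Figures were drawn with matplotlib 3.10.9.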

Results

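Gene expression was compared between heads of Drosophila melanogaster males withdrawn from pentylenetetrazol (PTZ) and heads of untreated males. PTZ is a convulsant that blocks GABA-A receptors. Unmated males of the Oregon-R wild-type stock were kept 30 to a vial, ate food with PTZ at 8 mg/ml for 7 days and were then returned to normal food. Heads were taken at day 8, day 10 and day 14 from the start of the treatment, that is after 1, 3 and 7 days of withdrawal. By its title, the study asked which expression changes follow one another as withdrawal proceeds. Each day had 4 spotted cDNA arrays of 2 colours, and each array set heads of treated flies directly against heads of untreated flies of the same day. The labels describe the 4 arrays of a day as biological replicates, each from its own pools of heads.

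The arrays carried 27648 spots, and the spots with a deposited value differed between days. Day 10 arrays held 15057 to 18354 values and day 14 arrays 4310 to 19807, while the day 8 columns held 2316 to 7454. The small number of arrays limits the precision of every mean below. Wherever 2 of the 4 day 8 columns both held a value, the values were identical (4790 of 4790 spots for replicates 1 and 2, largest difference 0). The 4 columns were therefore counted as 1 sample. Whether they hold 1 array or a repeated mean of 4 is not given in the sources used here.

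Signed values are read as PTZ-withdrawn over untreated. This direction is taken from the channel labels and is not settled. The channel labels put the treated heads in the Cy5 channel of all 12 arrays, the series text states that 2 of 4 arrays per day had swapped dyes, and the labelling text of day 10 replicates 1, 2 and 3 names Cy3 for the treated heads. No pair of samples correlated below an r of -0.207 across genes. Most arrays of 1 day correlated little with one another, so this does not settle the direction. The median log2 ratio of a deposited column lay between 0.16 and 0.194 at day 8, between -0.309 and -0.198 at day 10 and between 0.558 and 1.588 at day 14. The median of each array was set to 0, so every value below is relative to the median of the genes on its array.

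At day 8, after 1 day of withdrawal, higher and lower hold only if the channel labels do, and a turned sign would reverse them. The day has 1 sample, so every SE and adjusted p of that day rests on the spread of the other days. Under that assumption limma called 19 of 519 genes tested, 4 higher and 15 lower in the withdrawn heads, against 4 with the spread raised as described below, and 40 had an unadjusted p under 0.05. Rpn13, a ubiquitin receptor of the proteasome, was highest at a log2 ratio of 1.76 (SE 0.23, adjusted p = 0.00140). CG1902 at 1.33, CG4594 at 1.32 and CG7974 at 0.82 were the other genes called higher. The lowest were Map60, a microtubule-associated protein of the centrosome, at -4.32 (SE 0.22, adjusted p = 2.21e-05), CG11474 at -4.13 and U2af50 at -3.63 (SE 0.23, adjusted p = 2.45e-06). U2af50 encodes the large subunit of the factor that recognises 3' splice sites. CG1971 at -3.10 and Nadsyn, the NAD synthetase, at -2.22 followed. Dhdds stood at -1.53 and the ceramide kinase gene Cerk, measured on 1 spot, at -1.47. The histone acetyltransferase gene Atac2 at -1.22, CG3719 at -1.19 and CG4853 at -1.17 completed the 10 lowest. Gabat, the GABA transaminase, stood at 0.03 (SE 0.24, adjusted p = 0.991). The translation list, the only gene list with at least 5 genes tested at this day, had a median of -0.05 over 6 genes, 5 of them below 0, and 26.05% of 10000 random lists of that size had a lower median.

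The values of day 8 speak against that assumption, since its spots were noisier than those of the other days: differences between twin spots had an SD of 0.589 to 0.755 in the day 8 columns, 0.270 to 0.414 at day 10 and 0.245 to 0.443 at day 14. With the day 8 spread raised 1.85 times, the ratio of the day 8 SD to the median of the others, a test chosen after seeing the data, 4 of the 19 genes were still called, CG11474, CG1971, Map60 and U2af50, and none higher. The adjusted p above do not take the noisier spots into account. Among the 19 genes, 6 were measured on 1 spot and 7 had spots more than 1 apart on the log2 scale, among them CG11474, CG1971, Map60, Nadsyn and CG7974. Leaving such spots out gave 11 calls, the values as deposited gave 8, and leaving out the column of replicate 3, which had the fewest spots, gave 30. Of the 19 genes, 10 lay within 24 spots of another called gene in the order of spot numbers, against a median of 2 in 10000 random sets of 19 tested genes.

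**Figure D1:**
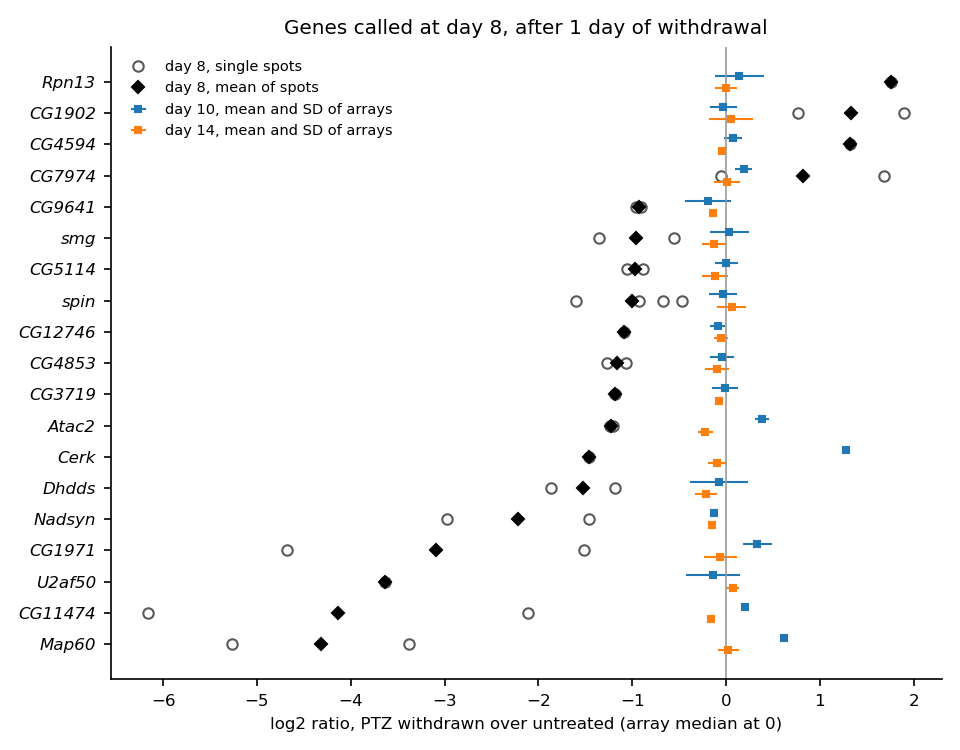
Each line is 1 of the 19 genes called at day 8, and the horizontal axis is the log2 ratio of PTZ-withdrawn over untreated heads. Open circles are single spots of day 8, diamonds their mean, and squares the means of the day 10 and day 14 arrays with SD; the spots of CG11474 lie 4.05 apart and those of Atac2 0.024 apart.

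At day 10, after 3 days of withdrawal, no gene of 4661 passed an adjusted p of 0.05 in limma, whose smallest adjusted p was 0.0591, and 616 genes had an unadjusted p under 0.05. One-class SAM, the method the study names, called 24 genes, all higher. Among the 5 genes above 0 with the smallest p were CG30111 at 1.38 ± 0.45 (SD, n = 3), CG9682 at 1.23 ± 0.15 (n = 3) and CG1647 at 0.87 ± 0.20 (n = 3). The glucose transporter gene Glut1 stood at 1.03 ± 0.19 (n = 3, adjusted p = 0.0702) and CG14546 at 0.66 ± 0.17 (n = 4). Below 0, SKIP, which encodes a protein that binds the Shal potassium channel, had the narrowest spread at -0.50 ± 0.07 (n = 4, adjusted p = 0.0736). Its value at day 8 was -0.56 and its day 14 mean was -0.06 ± 0.07 (n = 4). Rassf, a Hippo pathway regulator, stood at -0.64 ± 0.18 (n = 4) and CG14889 at -0.71 ± 0.22 (n = 4). CG8195 at -0.60 ± 0.12 and Bili at -0.59 ± 0.12 (both n = 4) were the others. All 10 genes had the same sign on every array that measured them, and at an adjusted p under 0.1 limma called 12 genes, 6 higher and 6 lower.

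The count at day 10 moved with single arrays. Without replicate 1 limma called 134 genes, 124 of them higher if the channel labels hold, without replicate 2 it called 42, and without replicate 4 it called 1. With the signs of replicates 1, 2 and 3 turned, as their labelling text would have it, all of the 12 genes named at day 10 by rule changed sign. With replicates 3 and 4 turned 9 did, with 2 and 4 turned 5, and with 2 and 3 turned 9. No gene was called under any of these 4 settings, and the directions at day 10 rest on the channel labels. The arrays fell into 2 pairs, with an r of 0.51 across genes between replicates 1 and 2, 0.56 between replicates 3 and 4, and -0.06 to 0.02 between the pairs. A dye term that set the first pair against the second gave 40 calls, 26 of them higher. That term takes the difference between the pairs out of the spread. The fit counts the 4 arrays as independent. The arrays of a pair may share biology or effects of place on the slide. The SEs and p of day 10, with or without the term, may then be too small.

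**Figure D2:**
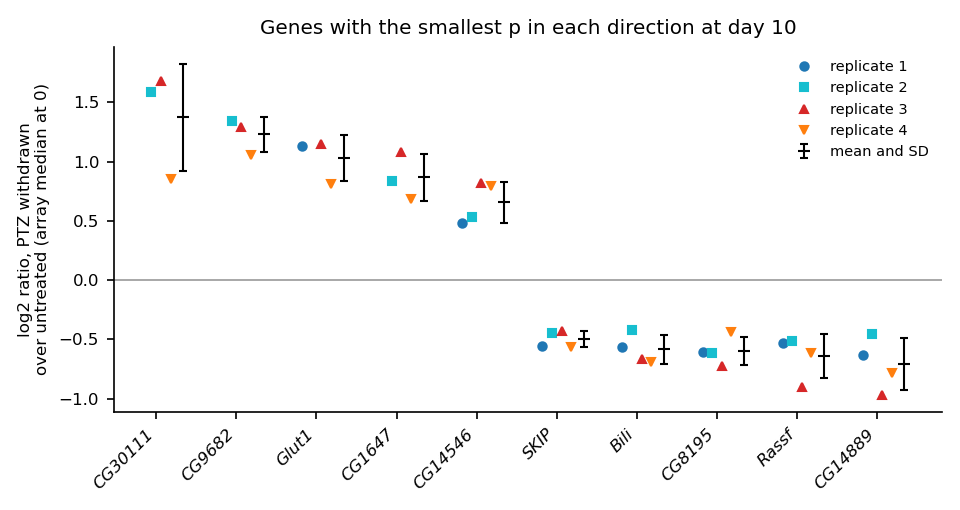
The vertical axis is the log2 ratio of PTZ-withdrawn over untreated heads at day 10, for the 5 genes above and the 5 below 0 with the smallest p. Symbols are single arrays and the bars give mean and SD; SKIP lies at -0.50 with an SD of 0.07.

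None of the 31 gene lists tested at day 10 passed cameraPR, the gene list test of limma. This count changed in 9 of 17 alternatives, to at most 3, in the values as deposited. GABA signalling, the system PTZ acts on, had all 5 tested members below 0 (median -0.11, adjusted p = 0.227), among them Gad1, which makes GABA, at -0.21 ± 0.22 (SD, n = 4), the receptor subunit gene Lcch3 at -0.10 ± 0.19 (n = 4) and the GABA transporter gene Gat at -0.29 ± 0.38 (n = 4). The list also holds Rbp9, an RNA-binding protein gene, at -0.11, and Ssadh at -0.01 (SE 0.11). Gat, Rbp9 and Ssadh were named after their values were seen. Over the members measured on each array, the list medians of replicates 1, 2, 3 and 4 were -0.184, -0.135, 0.066 and -0.0145. Circadian clock genes had a median of -0.15, with 7 of 11 below 0 and an adjusted p of 0.0526 with the preset correlation. With the estimated correlation between these genes, 0.466, the adjusted p was 0.744 in cameraPR. The fat body markers had a median of 0.22, with 14 of 17 above 0 (adjusted p = 0.0921). Replicate 4 stood at 0.56 and replicates 1, 2 and 3 at 0.051, -0.049 and 0.084, so 1 array carried most of it. The female germ line markers had a median of 0.27, with 7 of 7 above 0 (adjusted p = 0.137), and stood at 0.60 in replicate 4 and at 0.21, 0.14 and 0.13 in replicates 1, 2 and 3. Of these 7, 3 are yolk protein genes (Yp1, Yp2 and Yp3, named after their values were seen) that the fat body list holds too, so the 2 lists are not independent. The testis markers had a median of 0.29 over 8 genes (adjusted p = 0.0526) and stood at 0.0605 and 0.0698 in replicates 1 and 2 and at 0.415 and 0.51 in replicates 3 and 4. No correlation between genes could be estimated for the testis list. Adjusted over the list alone, 13 members passed at day 10, against 0 over all genes tested. The 9 lower ones included acetylcholinesterase (Ace, -0.55 ± 0.17), the choline transporter gene ChT (-0.46 ± 0.19), Rab3 of the synaptic vesicle (-0.67 ± 0.33) and the Fos gene kay (-0.34 ± 0.13), each with n = 4. Pdp1, Rh7 and slmb of the clock list, Galphai and eIF4B were the others. The 4 higher ones were PGRP-LB, a regulator of the immune response, at 0.79 ± 0.39 (n = 4), Fst at 0.58 ± 0.08 (n = 4), and the testis markers S-Lap8 at 1.10 and twe at 0.62. These 13 genes were named after their values were seen.

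At day 14, after 7 days of withdrawal, genes of oxidative phosphorylation were higher as a group under a preset correlation between genes, if the channel labels hold. Of 26 members tested 20 lay above 0, with a median log2 ratio of 0.12 and an adjusted p of 0.00155 in cameraPR with a preset correlation. With an estimated correlation between genes the adjusted p = 0.337 in cameraPR. Over the members measured on each array, the list medians of replicates 1, 2, 3 and 4 were 0.09, 0.02, 0.27 and 0.21. ND-B17.2, a complex I subunit gene, stood at 0.33 ± 0.09 (SD, n = 4), the cytochrome c oxidase subunit gene levy at 0.36 ± 0.17 (n = 3) and ND-13B at 0.38 ± 0.26 (n = 3). ATPsynE stood at 0.26 ± 0.08 (n = 4) and UQCR-6.4 lowest at -0.11 ± 0.16 (n = 4); ND-13B, ATPsynE and UQCR-6.4 were named after their values were seen. At day 10 the same list had 23 of 30 members above 0 and a median of 0.06 (adjusted p = 0.233), and the difference from day 10 to day 14 was above 0 for 11 members and below 0 for 14 (median -0.018, adjusted p = 0.605), with no member called. Tests chosen after seeing the data turned the signs of 2 arrays of day 14, since the swapped arrays are not known. The median was then -0.043 with replicates 3 and 4 turned (8 of 26 above 0, adjusted p = 0.201), 0.038 with 2 and 4 turned (17 above 0, adjusted p = 0.769) and -0.024 with 2 and 3 turned (11 above 0, adjusted p = 0.753). With a dye term in these 3 pairings the list passed each time (adjusted p of 0.000310 to 0.0380). Such a term leaves the day mean nearly as it was (medians of 0.106 to 0.115), so it cannot test which arrays were swapped. With the medians of print blocks and places set to 0, an alternative chosen after seeing the data, its day 14 median was 0.069 (adjusted p = 0.0480). The vacuolar ATPase had all 8 tested members above 0 (median 0.16, adjusted p = 0.125), and no other list of the 26 tested passed. Without replicate 3 the adjusted p of the oxidative phosphorylation list was 0.344, at a median of 0.10, and no list passed. Without replicate 1, 3 lists passed.

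No single gene of 3010 passed at day 14 in limma, 200 had an unadjusted p under 0.05, and SAM called 0. Above 0, the genes with the smallest p were mtg, which organises the synaptic matrix, at 0.63 ± 0.27, the mitochondrial ribosome gene mRpS18B at 0.53 ± 0.11, trn at 0.65 ± 0.47, CG14689 at 0.56 ± 0.14 and CG6055 at 0.41 ± 0.05 (all SD, n = 3). Below 0 were CG6296 at -0.75 ± 0.12 (n = 3), CG31974 at -0.88 ± 0.59 (n = 4), Noc2 of ribosome assembly at -0.85 ± 0.52 (n = 3), CG18004 at -0.73 ± 0.33 (n = 3) and cnk, a scaffold of Ras signalling, at -0.40 ± 0.23 (n = 4). These 5 lie above 0 in the values as deposited, where 3001 of 3010 genes were called higher. Gad1 stood at 0.14 ± 0.13 and Gabat at 0.07 ± 0.24 (both n = 4). Adjusted over the list alone, 1 list member passed, the tyrosine hydroxylase gene ple at 0.48 ± 0.16 (n = 3), named after its value was seen.

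Differences between days were tested themselves. If the channel labels hold, the fat body markers fell from day 10 to day 14 relative to the array medians, with 10 of 11 members lower. The median difference was -0.33 (adjusted p = 0.0375 in cameraPR over 25 lists). The estimated correlation was -0.22 and entered as 0, below the preset 0.01. Its adjusted p of 0.0175 in cameraPR, over 20 lists, is therefore no stricter test. In the values as deposited the median difference was 1.16. There 2352 of 2385 genes were called higher, so this sign holds the offsets of the columns. Desat1, a fatty acid desaturase gene, differed by -0.64 (SE 0.28) and Fst by -0.40 (SE 0.17). The yolk protein genes Yp1 and Yp3, which are members too and are expressed in the female fat body, differed by -0.87 (SE 0.53) and -0.64 (SE 0.32). FASN1, the fatty acid synthase gene, went the other way by 0.18 (SE 0.22), and Yp1, Yp3 and FASN1 were named after their values were seen. The list did not pass without day 10 replicate 1 (median difference -0.42, adjusted p = 0.168), 2 (-0.33, 0.12) or 4 (-0.22, 0.440), and without day 14 replicate 2 (-0.24, 0.143), 3 (-0.25, 0.172) or 4 (-0.27, 0.0544). It passed without day 10 replicate 3 (-0.20, 0.0296) and without day 14 replicate 1 (-0.40, 0.0252). With the signs of day 10 replicates 1, 2 and 3 turned, chosen after seeing the data, the median difference was -0.06. Then 7 of 11 members were lower (adjusted p = 0.497 in cameraPR). In the main fit none of the other 24 lists passed.

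No gene of 2385 passed from day 10 to day 14 in limma, 172 had an unadjusted p under 0.05, and 3 genes passed without day 10 replicate 1. The smallest p belonged to wus at a difference of -1.63 (SE 0.29), CG30111 at -1.24 (SE 0.24) and CG5107 at -1.21 (SE 0.24). Adjusted over the list alone, 1 list member passed, the vacuolar ATPase gene Vha26 at a difference of 0.62, named after its value was seen.

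From day 8 to day 10, 8 of 488 genes passed under the same borrowed spread, with 5 differences above and 3 below 0, and from day 8 to day 14, 12 of 445 passed, with 9 above and 3 below 0. With the day 8 spread raised these counts were 2 and 4. All 8 and all 12 had been called at day 8, and these comparisons share the day 8 sample, so their calls are not independent and mainly restate that sample. U2af50, measured on 1 spot at day 8, differed by 3.49 (SE 0.25, adjusted p = 1.14e-05) from day 8 to day 10 and by 3.70 (SE 0.25, adjusted p = 5.64e-06) to day 14, where its mean was 0.07. CG1971 differed by 3.43 to day 10 and by 3.03 to day 14, Dhdds by 1.45 to day 10, CG3719 by 1.18 and CG4853 by 1.12. Map60 differed by 4.35, CG11474 by 3.97 and Nadsyn by 2.07 from day 8 to day 14. Rpn13 differed by -1.62 to day 10 and by -1.76 to day 14, CG1902 by -1.36 and -1.29, and CG4594 by -1.25 and -1.36. Without the day 8 column of replicate 3 these counts were 13 and 19. Without day 10 replicate 1 and without day 10 replicate 2 the first was 5 and 3, and without day 14 replicate 4 the second was 7. With the day 8 spread raised U2af50 had an adjusted p of 0.00267 and 0.00139, and no difference below 0 passed.

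Across the mean of the 3 days, 10 of 419 genes passed, 4 higher and 6 lower, and 9 of them had been called at day 8. Rpn13 at 0.63, CG1902 at 0.45, CG4594 at 0.45 and CG7974 at 0.34 were higher. U2af50 at -1.23, CG1971 at -0.94, Dhdds at -0.61, CG4853 at -0.44 and CG9641 at -0.42 were lower. The 10th gene was SKIP at -0.37, named after its value was seen, with a day 14 mean of -0.06. The count was 6 without day 10 replicate 1 or 2 or day 14 replicate 1, 3 without day 14 replicate 3, and 2 with the day 8 spread raised. The mean of days 10 and 14 alone, chosen after seeing the data, gave 0 calls in limma, with 303 genes at an unadjusted p under 0.05.

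Correlations between days were low across genes, which are not independent replicates, but so were most of those between arrays of 1 day. Day 14 arrays had a Pearson r of -0.02 to 0.23 with one another, and day 10 arrays -0.06 to 0.02 between the pairs but 0.51 and 0.56 within them, so the values below do not show that the days differ. Day 8 and day 10 had a Pearson r of 0.203 and a Spearman rho of 0.369 over 488 genes. Day 8 and day 14 had 0.134 and 0.139 over 445 genes, and day 10 and day 14 had 0.132 and 0.15 over 2385 genes. With the medians of print blocks set to 0, chosen after seeing the data, r was 0.0249 between days 8 and 10 and 0.0296 between days 8 and 14.

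**Figure D3:**
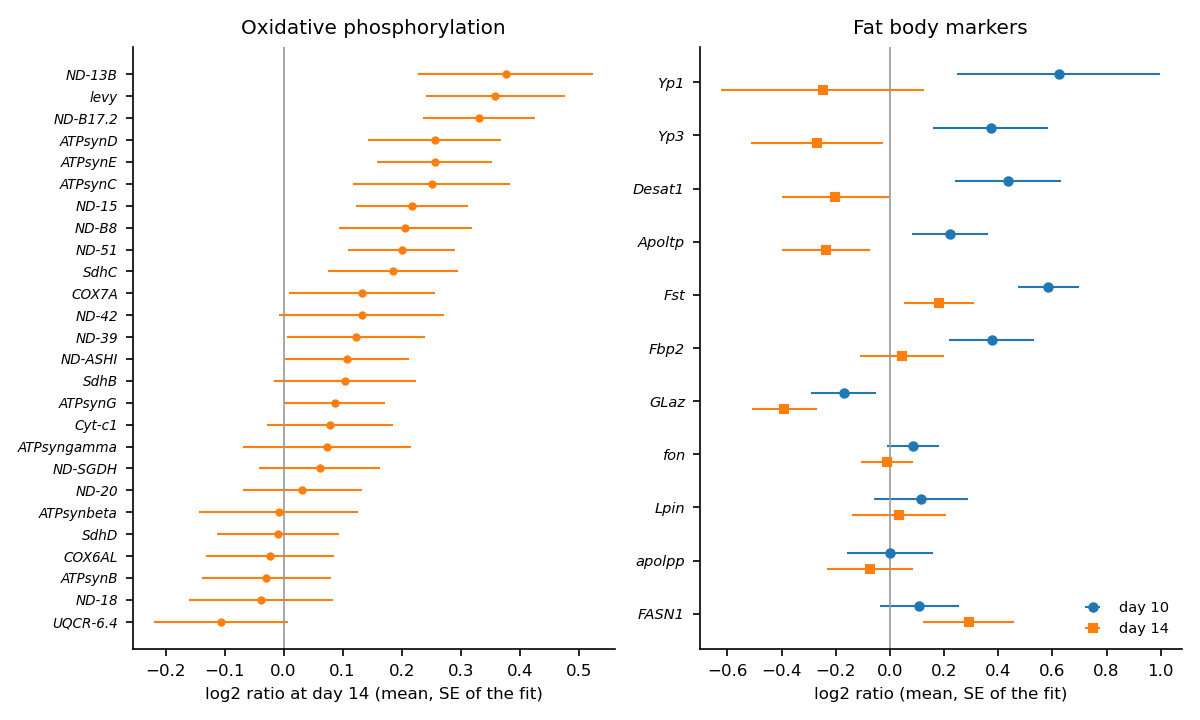
Mean log2 ratios with the SE of the fit, for 26 oxidative phosphorylation genes at day 14 and for 11 fat body markers at day 10 and day 14. Of the first, 20 lie above 0. Of the second, 10 are lower at day 14 with array medians at 0. The list's median difference is 1.16 in the values as deposited, where 2352 of 2385 genes were called higher.

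**Figure D4:**
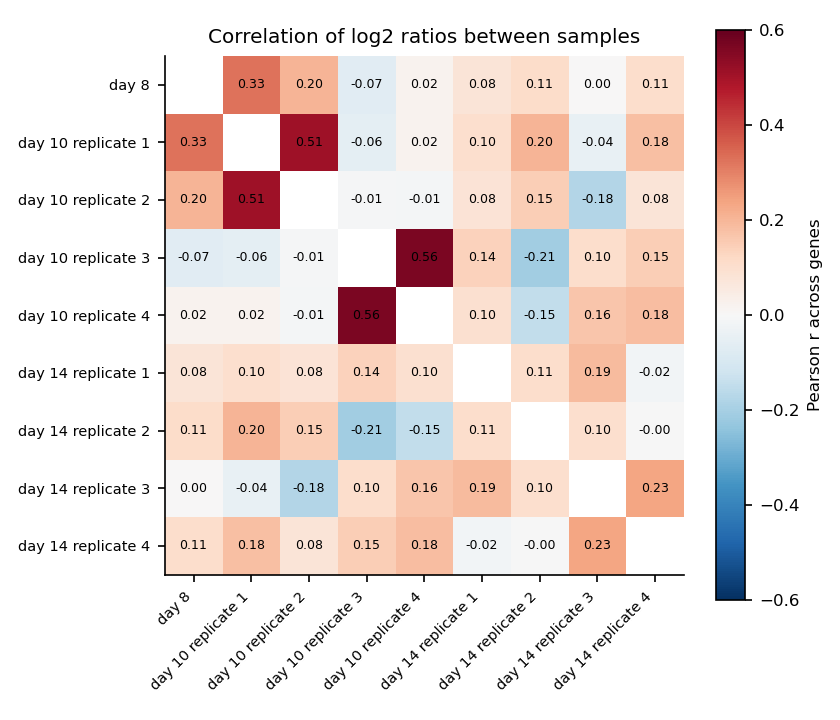
Pearson r across genes between the log2 ratios of the 9 samples, with day 8 as 1 sample and 4 arrays each of days 10 and 14. The highest values are 0.56 between day 10 replicates 3 and 4 and 0.51 between day 10 replicates 1 and 2, and the lowest is -0.21.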

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

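The tests of the differences between days and the 2 counts of splits of the arrays were planned. The differences from day 8 had been planned with its columns as separate arrays. The tests of muscle, yolk protein genes, spot noise, raised spread, print blocks and places, and neighbouring spots were chosen only after the result was seen.

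The genes called from day 8 to day 10 (8) and from day 8 to day 14 (12) stand out as differences between time points, and all of them belong to the 19 genes called at day 8. Noise of single spots may be part of the cause: 7 of the 13 called genes with several spots had spots more than 1 apart, against 25 of 509 tested genes with several spots, and the highest of 10000 random sets of 13 had 4. With the day 8 spread raised 1.85 times, the ratio of the SDs of twin spots, the calls were 4 at day 8, 2 from day 8 to day 10 and 4 from day 8 to day 14. Noise stays open too for the 6 genes with spots within 1 of each other and for the 6 on 1 spot. A trend over print blocks and places is argued against as the whole cause, since 15 of the 19 genes were still called after those medians were set to 0. A local fault of the slide may still contribute, since 10 of the 19 had another called gene within 24 spots, which 0.03% of 10000 random sets reached. A response in the first day of withdrawal stays open, as untested, because the 4 columns of that day hold 1 set of values.

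The fat body markers differed between day 10 and day 14, with an adjusted p of 0.0375 and a mean difference of -0.33 (SE 0.09 over genes). Muscle from trunks among the sieved heads is argued against, since the muscle markers had a mean difference of 0.11 (SE 0.05 over genes), of the other sign. This covers muscle only, and other trunk tissue was not tested. The testis markers with a tested difference, Pglym87, ocn and Mst77F, differed by -0.70, -0.21 and -0.20 (SE of the fit 0.22, 0.42 and 0.17). They were named after their values were seen. With the medians of blocks and places set to 0 the mean difference was -0.29 (SE 0.10) and the median -0.09, and 10 of 11 members were below 0. The adjusted p was 0.185 in cameraPR, and the SD over genes went from 0.31 to 0.33. Place on the slide may therefore be part of it. Without Yp1 and Yp3, the yolk protein genes with a tested difference, 9 genes were left, with a mean difference of -0.24 (SE 0.08). The adjusted p was 0.228 in cameraPR, and the SD over genes went from 0.31 to 0.25. It stays open that female flies in some pools may contribute. Chance could not be excluded, since 7 of the 35 splits of the 8 arrays into 4 and 4 gave as many lists as the 1 of the real split, and the highest of the others gave 2.

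For genes called from day 10 to day 14 the real split gave 0, as did all 35 splits, and the highest of the others was 0, so the count says nothing against chance. Lcch3 stood at 0.19 in day 10 replicate 4, apart from -0.21 to -0.18 in the other 3 arrays of that day. The value of cnk was 0.0505 in day 10 replicate 4, apart from -0.15 to -0.12 in the others. Chance sets apart about 1 in 20 groups of arrays, and 47 groups of 4 were looked at.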

How the results depend on the processing

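The tests with twin spots left out, with medians of print blocks and places set to 0, with the day 8 spread raised, with the mean of days 10 and 14 alone and with dye terms or turned signs in the gene lists or dye terms in the difference were chosen only after the result was seen, and the others were planned.

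Of 1492 values of named genes and of the 2 lists that passed, 1288 kept direction and side of the threshold, 127 lost the call, 62 gained it and 15 changed sign. Turned signs of single genes are not in this tally. With day 10 replicates 1, 2 and 3 turned, 12 of 12 genes named at day 10, 0 of 8 from day 8 to 10, 3 of 5 from day 10 to 14 and 0 of 9 in the mean of 3 days changed sign. With 2 replicates turned, 9 (3 and 4), 5 (2 and 4) and 9 (2 and 3) of 12 did at day 10, and 5, 3 and 10 of 14 at day 14. The oxidative phosphorylation median was -0.0426 with day 14 replicates 3 and 4 turned, -0.0237 with 2 and 3 and 0.038 with 2 and 4, with 0 lists passing each time, and the fat body median from day 10 to 14 was -0.058 with day 10 replicates 1, 2 and 3 turned. The count of 0 at day 14 held in 24 of 26 alternatives, the count of 0 from day 10 to day 14 in 25 of 27 and the count at day 8 within 1.5 times in 12 of 19. Of these 19, 4 leave out 1 of the identical day 8 columns, which changes only the genes tested (519 to 1077 without replicate 3) and shows nothing about the values. The oxidative phosphorylation list at day 14 passed in its direction in 15 of 20 alternatives (adjusted p 8.37e-05 to 0.769 in cameraPR). Among the 15 are the dye terms in 3 pairings, which leave the day mean nearly unchanged. The fat body list from day 10 to day 14 passed in 5 of 21 (adjusted p 0.00345 to 0.497 in cameraPR). Its lowest adjusted p came from the values as deposited, which are not among the 5 because the median was above 0. There 2352 of 2385 genes were called higher, so that sign holds the column offsets. The count of 0 genes at day 10 held in 15 of 27 alternatives, and the count in the mean of 3 days within 1.5 times in 15 of 29. The count of 0 lists at day 10 held in 8 of 17. The count of 1 list held in 14 of 20 at day 14 and in 7 of 22 from day 10 to 14. The correlation of days 10 and 14 moved by less than its spread in all 15. Where no reason is given, the cause was not tested. Signal over background was not analysed here, and single arrays with few spots limit what can be tested.

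With the values as deposited, each column keeps its own offset. The calls were 8 at day 8, 3001 at day 14, 167 in the mean of 3 days, 4 from day 8 to 10, 24 from day 8 to 14 and 2352 from day 10 to 14, and 3 lists passed at day 10. CG6296 was then 0.49, Noc2 0.39, CG31974 0.19, CG18004 0.51 and cnk 0.67 at day 14, and CG30111 was 0.27, CG5107 0.27, Fst 0.74, Desat1 0.85 and the fat body list 1.16 from day 10 to 14. With equal spread of the arrays 16 genes passed in the mean of 3 days, and 2 lists at day 10 and 0 from day 10 to 14.

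With a value required in all 4 columns fewer genes were tested: 6 passed at day 8, 3 at day 10, 2 in the mean, 1 from day 8 to 10 and 1 from day 8 to 14, with 2 lists at day 10, 0 from day 10 to 14 and an r of 0.0633 between days 8 and 14. With 2 of 4 columns, and so more genes, 29 passed at day 8, 15 from day 8 to 10 and 19 from day 8 to 14, with 2 lists at day 10 and 0 from day 10 to 14. With 1 probe per gene 3 genes passed at day 10 and 6 in the mean, with 1 list at day 10 and 0 from day 10 to 14. Each probe alone gave 77 at day 8 and 1 at day 10.

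Only the arrays of days 8 and 10 gave 2 calls for that difference, array weights 12 at day 10, and SAM 24 at day 10. The replicate block gave 5 calls at day 10 and 4 from day 8 to 14 and moved no other count by over 1.5 times. Over the 604 genes on all 8 arrays, the deviations of same-numbered arrays of days 10 and 14 from the day means correlated at 0.0172, 0.342, 0.252 and 0.159, and only replicates 2 and 3 correlated best with their own number, so the numbers do not pair the arrays. Day 10 replicates 1 and 2 both correlated best with day 14 replicate 2 (0.368 and 0.342), and replicates 3 and 4 with day 14 replicate 3 (0.252 and 0.421). The check therefore does not show that the arrays of days 10 and 14 are independent, which the test of their difference assumes. A dye term at day 10 gave 40 calls and 1 list for replicates 1 and 2 against 3 and 4, and 1 call and 2 lists for 1 and 4 against 2 and 3. At day 14 replicates 1 and 3 against 2 and 4 gave 1 call. In the difference from day 10 to 14 the first and the last of these day 10 pairings left 0 lists. With the signs of day 10 replicates 1, 2 and 3 turned 6 genes passed in the mean. At a threshold of 0.1, 12 passed at day 10 and 18 in the mean.

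With twin spots over 1 apart left out 11 genes passed at day 8, all among the 19, and 4 from day 8 to 14, with 2 lists at day 10 and 0 from day 10 to 14. With medians of print blocks set to 0 the mean gave 4 calls, the lists from day 10 to 14 gave 0, Gabat at day 8 was -0.0435, and r was 0.0249 between days 8 and 10 and 0.0296 between days 8 and 14. With places as well the mean gave 6, the lists 0, Gabat -0.0846 and r 0.0210 between days 8 and 14. With the day 8 spread raised by the SD of its twin spots 4 genes passed at day 8, 2 in the mean, 2 from day 8 to 10 and 4 from day 8 to 14. The mean of days 10 and 14 alone gave 0. With an estimated correlation between genes 0 lists passed at day 14.

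Leaving out 1 replicate at a time gave 19 to 30 calls at day 8 (highest without day 8 replicate 3), 0 to 134 at day 10 (highest without replicate 1), 0 to 0 at day 14, 3 to 11 in the mean, 3 to 13 from day 8 to 10, 7 to 19 from day 8 to 14 and 0 to 3 from day 10 to 14. Lists that passed ran from 0 to 1 at day 10, from 0 to 3 at day 14 and from 0 to 1 from day 10 to 14. Gabat at day 14 ran from -0.005 without replicate 4 to 0.17 without replicate 1, r between days 8 and 10 from 0.142 to 0.239, between days 8 and 14 from 0.0859 to 0.149, and between days 10 and 14 from 0.0479 to 0.174. Day 8 alone, SAM, dye terms and turned signs at day 8 were not run, since 1 sample has no spread of its own.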

Other observations

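All tests of explanations here were chosen only after the result was seen.

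Most gene groups of neuronal signalling and metabolism did not pass their test at day 10 or day 14. Ion channels and pumps of excitability had medians of 0.01 at day 10 and 0.09 at day 14, synaptic vesicle genes -0.08 and 0.02, and neuropeptides with their receptors 0.00 and 0.06. Glutamate signalling stood at 0.00 and 0.16, monoamine genes at -0.09 and 0.04, and learning and memory genes at -0.10 and 0.03. Heat shock proteins and chaperones stood at 0.04 on both days, the proteasome at 0.14 and 0.08, and glycolysis with the TCA cycle at 0.04 and -0.04. Cytochrome P450s had medians of -0.06 and 0.03, with 28 of 46 members below 0 at day 10, and cytosolic ribosomal proteins 0.11 and 0.03, with 15 of 19 above 0 at day 10 (adjusted p = 0.118). All of these are relative to the array medians.

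The yolk protein genes, which females express in the fat body, were measured in heads labelled male. Yp1 stood at 1.66 at day 8, 1.95 in day 10 replicate 4 and -0.995 in day 14 replicate 3, and between -0.17 and 0.17 in the other 4 arrays that measured it. Yp3 stood at 1.00, 1.12 and -0.91 in the same samples, and both spots of each gene were on the same side. The female-biased gene fit stood at 0.06 at day 8 and -0.74 in day 14 replicate 3. Yp2 stood at 0.77 in day 10 replicate 4 and between -0.17 and 0.39 in the other 4 arrays that measured it. Among genes higher in males, Obp99b stood at 0.17 at day 8, 0.74 in day 10 replicate 4 and 1.19 in day 14 replicate 3, and ran from -1.34 in day 14 replicate 2 to 1.59 in day 14 replicate 1. In day 14 replicate 3 Cyp4d21 stood at 0.84. At day 10 Obp99b, sxe2 and Cyp4d21 were each lower in replicates 1 and 2 than in replicates 3 and 4. In the order of replicates 1 to 4, Obp99b stood at -0.14, -0.16, 0.87 and 0.74 and sxe2 at -0.11, -0.05, 0.51 and 0.57. Cyp4d21 stood at -1.07, -0.75, 0.06 and 0.11. These 7 genes were named after their values were seen.

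The day 10 arrays correlated in 2 pairs, replicates 1 with 2 and 3 with 4. The slide series is argued against as the whole cause, since replicates 3 and 4 came from different series and had an r of 0.564. After the medians of blocks and places were set to 0, the pair correlations fell from 0.509 and 0.564 to 0.383 and 0.407. A trend over print blocks and places is therefore also argued against as the whole cause. Before that step, neighbouring clones in the order of spot numbers correlated at a Spearman rho of 0.417 to 0.538 on the day 10 arrays. Local effects of place that such medians leave in may therefore contribute. A fixed dye bias under opposite dye orientations may contribute: the difference between the means of the pairs correlated with day 14 replicate 2 at 0.290 and with day 14 replicate 3 at -0.275, which fell to 0.166 and -0.130 after the medians of blocks and places were set to 0, and with replicate 1 at an absolute r of only 0.0410 before it, so dye orientation cannot be told apart from biology shared by 2 pools. Of the 35 splits of the 8 arrays, the split that put day 10 and day 14 replicates 1 and 2 together had 430 genes at an unadjusted p under 0.05, against 172 between the days.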
